A study of Drosophila montana and Drosophila virilis with 10 samples.

How the data were processed

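Messenger RNA of whole flies was sequenced on SOLiD instruments in 10 libraries from 2 species of the Drosophila virilis group, D. montana and D. virilis, after cold acclimation or maintenance at ambient temperature. Each library was made from a pool of whole flies, 10 per pool in D. montana and 20 per pool in D. virilis, per the labels' source names. The groups came from the sample titles: 3 control and 3 acclimated libraries of D. montana, and 2 control and 2 acclimated libraries of D. virilis. Each species is represented by 1 strain, per the labels. The labels do not say whether the replicate pools came from separate cultures, so p-values measure the spread between these pools, which may be partly technical. The series text names 2 SOLiD models without saying which library ran on which. RNA was extracted with Tri Reagent and purified on RNeasy columns with DNase treatment, per the labels' protocols.

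The deposited values are raw read counts per gene identifier, made with HTSeq per the submitters' processing notes. The aligner, genome build, annotation and counting mode are not given in the sources used here. All 10 files hold the same 15342 identifiers, of which 15341 have the FlyBase gene form and 1 the transcript form, so reads of both species were counted against 1 annotation. The table of gene names used here covers a D. montana assembly and holds 0 of these identifiers. Genes are therefore reported by identifier. The 22 gene lists fixed before the data were examined could not be matched to identifiers, and 0 of them were tested. For the same reason no coordinates are given.

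The last 5 lines of each file are counters that name no gene, and they were left out of library sizes and tests. The counters for low alignment quality and for unaligned reads are 0 in every file. Reads aligned to more than 1 place made up 18.4% to 23.8% of the reads in the D. montana files and 75.6% to 83.4% in the D. virilis files. Whether this counter holds each such read once or once per alignment is not stated. Totals and shares of reads are therefore those counted in the files and may differ from shares of the sequenced reads. Reads outside annotated genes made up 53.1% to 56.6% in D. montana and 8.86% to 14.9% in D. virilis. Ambiguous reads made up at most 0.0026% of a file. Reads shared by near-identical genes would fall among the reads placed more than once, so counts of such genes are uncertain.

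The main test was edgeR 4.0.16 (quasi-likelihood F-test, with limma 3.58.1, in R 4.3.3) on the counts as deposited, with trimmed-mean (TMM) scaling, the default expression filter (minimum count 10, minimum total 15) by group and Benjamini-Hochberg adjustment. A gene was called at an adjusted p-value under 0.05. Each species was fitted alone. The difference in response between the species was the interaction contrast in a fit of all 10 libraries, each group with its own mean. Expression levels were not tested for differences between the species, since species cannot be separated from any difference in instrument, pool size or match to the annotation. Standard errors of log2 fold changes were taken as the unshrunken log2 fold change divided by the square root of F. Normalised read counts are in CPM over TMM-scaled library sizes within a species. Overlap of calls was tested with Fisher's exact test, one-sided. Sets of genes called in one species were tested in the other with limma's camera on voom values, with the inter-gene correlation preset to 0.01 and with an estimated correlation, and with fry, which tests whether a set's genes move on balance in 1 direction and does not compare the set with other genes. The tests of each species, the interaction, the overlap of calls and the correlation of fold changes were fixed before the data were examined. The set tests, the shares of genes with the same direction and the tests of read classes were chosen after the data had been seen.

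The rule for reported genes, fixed in advance for identifiers without names, allowed 2 that rose and 2 that fell per species, those with the largest fold change among called genes whose replicates did not overlap between groups, and up to 2 genes called in both species. FBgn0198817 was added after its values had been seen.

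Reads on genes numbered 1518027 to 2235850 per D. montana library and 650517 to 1316804 per D. virilis library. A count of 0 allows a level of up to 1.34 to 1.98 CPM in a D. montana library and 2.28 to 4.61 CPM in a D. virilis library (3 counts of the total, counting error only). In counts simulated for the tested genes with 200 changed genes, edgeR's test recovered 72.8% of changes of 1 log2 unit and 98.6% of changes of 2 log2 units with the D. montana libraries. With the D. virilis libraries it recovered 12% and 73.7%, and for the interaction 9.41% and 61.9%. False calls made up 8.18%, 10.1% and 4.70% of the simulated calls in D. montana, D. virilis and the interaction. The 200 genes were a smaller share of the genes than was estimated to change in the data. That estimate was 18.1% in D. montana, 17.3% in D. virilis and 14.6% in the interaction, so recovery in the data may differ. The interaction simulation gave both species 1 mean and 1 spread per gene. It therefore cannot show errors that arise where levels or spread differ between the species. No pair of replicates within a group agreed within counting noise, as 1 library deposited more than once would (chi-square per degree of freedom 3.78 to 9.45). This does not show whether they are biological replicates.

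The alternatives were DESeq2 1.42.0 size factors within edgeR, upper quartile scaling, library sizes without the 20 most abundant genes, DESeq2's Wald test, limma-voom with and without sample quality weights, 2 other filters, the replicate block, 1 fit of all libraries and leaving out each library in turn.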

Results

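The transcriptome of whole flies was measured in D. montana and D. virilis, 2 related Drosophila species, to ask which genes change with cold acclimation and whether the same genes change in both. The data comprised 3 control and 3 acclimated D. montana pools of strain 175OJ8 from Oulanka, Finland, and 2 control and 2 acclimated D. virilis pools of strain TOY3F9 from Toyama, Japan. The stated age rose by 1 day from each library to the next in the order of deposit, so it is uncertain whether the labels give true ages. It was 21 to 23 days after eclosion in the D. montana controls and 24 to 26 days in the acclimated pools, and 27 to 28 and 29 to 30 days in D. virilis. Acclimation and stated age therefore cannot be told apart within either species.

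The files held 5874251 to 9545667 reads per D. montana library and 6815826 to 16917956 per D. virilis library, most of which did not enter the gene counts. A gene received 25.5% ± 0.92 (SD, n = 3) of the reads in D. montana controls and 24.3% ± 1.8 (SD, n = 3) in acclimated flies. In D. virilis the shares were 9.55% ± 0.0035 (SD, n = 2) and 7.31% ± 0.66 (SD, n = 2). These shares include the reads aligned to more than 1 place. Without those reads, genes received 31.5% ± 1.2 (controls) and 30.9% ± 1.2 (acclimated) in D. montana. The same shares were 40.8% ± 2.5 and 43.2% ± 5.0 in D. virilis, so the order of the species and of the D. virilis groups turned. Reads aligned to more than 1 place made up 19.0% ± 0.08 (SD) of the control and 21.5% ± 2.8 of the acclimated reads in D. montana. The difference of 2.52 percentage points was within the spread of the acclimated pools (exact permutation test, two-sided p = 0.40; the smallest possible is 0.10). In D. virilis they made up 76.6% ± 1.4 of the control and 83.0% ± 0.44 of the acclimated reads, higher in both acclimated libraries, where 2 libraries per group cannot give a p below 0.333 in the exact test.

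**Figure D1:**
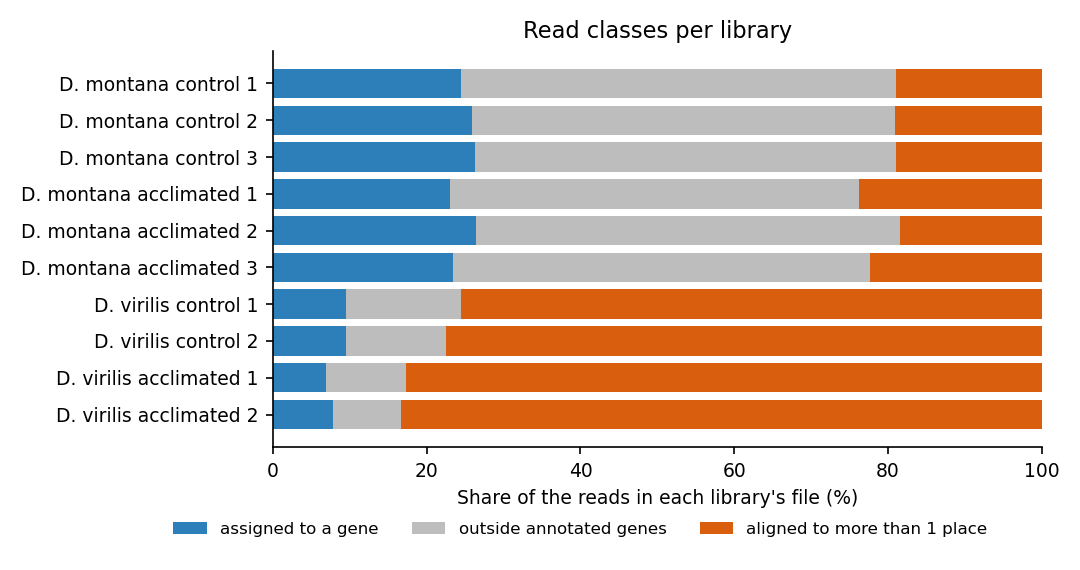
Share of the reads in each library's file (%, horizontal axis) assigned to a gene, lying outside annotated genes, or aligned to more than 1 place, 1 bar per library. Reads aligned to more than 1 place took 18.4% to 23.8% in the 6 D. montana libraries and 75.6% to 83.4% in the 4 D. virilis libraries.

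In D. montana, 156 of 9315 tested genes changed with acclimation, 108 upward and 48 downward (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The genes that rose had a median log2 fold change of 1.12 and took a larger share of the gene reads after acclimation, 1.59% to 1.75% in the acclimated libraries against 0.69% to 0.89% in the controls. The genes that fell had a median log2 fold change of −1.41 and took 0.38% to 0.48% against 0.99% to 1.44%. At least a 2-fold change was seen for 63 of the genes that rose and 38 of those that fell, and at least a 4-fold change for 3 and 11. Changed genes were found at all expression levels, with 16 that rose and 8 that fell among the 3105 least abundant tested genes, 38 and 18 among the next 3105, and 54 and 22 among the 3105 most abundant.

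Of the 2 largest increases among called genes, FBgn0198760 rose from 10.8 ± 6.3 to 81.4 ± 10.6 CPM (SD, n = 3 each). Its log2 fold change was 2.87 (SE 0.28, edgeR adjusted p = 0.00021). FBgn0207382 rose from 1.61 ± 1.42 to 10.5 ± 1.1 CPM, a log2 fold change of 2.72 (SE 0.50, edgeR adjusted p = 0.010), on only 1 to 5 reads per control library. The largest decreases among called genes were more than 10-fold. FBgn0209824 fell from 63.5 ± 31.4 to 4.0 ± 2.1 CPM, a log2 fold change of −3.97 (SE 0.42, edgeR adjusted p = 0.00035). FBgn0206059 fell from 45.1 ± 16.9 to 4.11 ± 2.26 CPM, a log2 fold change of −3.47 (SE 0.38, edgeR adjusted p = 0.00035). These 4 genes passed the threshold in every alternative that gave them an adjusted p-value, the highest being an edgeR adjusted p of 0.047.

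Unadjusted p-values were under 0.05 for 1247 D. montana genes, 13.4% of those tested. Control and acclimated libraries did not overlap for 18.6% of all tested genes, against 10% by chance. The number of calls depended on single libraries: it was 72 without control 2, 101 without acclimated 2 and 285 without control 3. Without control 1, 66 of 140 called genes rose (47.1%), and without control 3, 235 of 285 did (82.5%), against 69.2% with every library. Of the 156 genes, 52 were called in every fit that left out 1 library, and none changed sign in those fits.

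In D. virilis, 24 of 7692 tested genes changed with acclimation, 14 upward and 10 downward. All 24 changed by more than 2-fold, with a median log2 fold change of 2.07 among those that rose and −2.57 among those that fell. Of the changed genes, 21 lay among the 2564 most abundant tested genes, 3 among the next 2564 and 0 among the 2564 least abundant. In simulated counts, 12% of changes of 1 log2 unit were recovered in D. virilis, against 72.8% in D. montana. At that recovery, smaller D. virilis changes would mostly be missed, so the sizes of called changes do not compare the species. The genes that rose took 0.70% to 0.72% of gene reads in the acclimated libraries against 0.27% in the controls, and those that fell 0.076% to 0.098% against 0.53% to 0.62%. The share of reads aligned to more than 1 place was 6.49 percentage points higher in the acclimated D. virilis libraries.

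Among called genes, the largest increases in D. virilis were those of FBgn0211115 and FBgn0211278. FBgn0211115 rose from 18.9 ± 2.4 to 233 ± 5.6 CPM (SD, n = 2 each), a log2 fold change of 3.60 (SE 0.26, edgeR adjusted p = 0.0021). FBgn0211278 rose from 10.8 ± 3.0 to 82.7 ± 19.1 CPM, a log2 fold change of 2.95 (SE 0.40, edgeR adjusted p = 0.026). FBgn0210647 fell from 157 ± 123 to 3.37 ± 1.45 CPM, a log2 fold change of −5.57 (SE 0.72, edgeR adjusted p = 0.024), its control libraries differing by a factor of more than 3. FBgn0206925 fell from 192 ± 106 to 6.18 ± 5.64 CPM, a log2 fold change of −4.82 (SE 0.58, edgeR adjusted p = 0.023). FBgn0211115 passed in every alternative (adjusted p up to 0.032). Without control 2, which leaves 1 control library, the log2 fold changes of FBgn0211278, FBgn0210647 and FBgn0206925 were 2.71, −4.35 and −4.07. With limma-voom none of these genes passed (adjusted p = 0.078, 0.262 and 0.126). With sample quality weights the limma-voom adjusted p was 0.033, 0.391 and 0.187. DESeq2's Wald test gave no adjusted p-value for FBgn0211278.

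The D. virilis count was sensitive to single libraries and to the filter. It was 4 without control 2 (1 rose), 95 without acclimated 1 (46 rose), 214 without acclimated 2, 398 with no expression filter and 157 with a minimum of 1 CPM. The split between directions turned without control 1, where 7 of 29 called genes rose, and with library sizes taken without the 20 most abundant genes, where 11 of 27 rose (40.7%) against 58.3% with TMM scaling. Of the 24 genes, 2 were called in every fit that left out 1 library. Unadjusted p-values were under 0.05 for 986 genes, 12.8% of those tested, a share close to the 13.4% in D. montana. The biological coefficient of variation was 25.1% in D. virilis and 15.3% in D. montana.

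**Figure D2:**
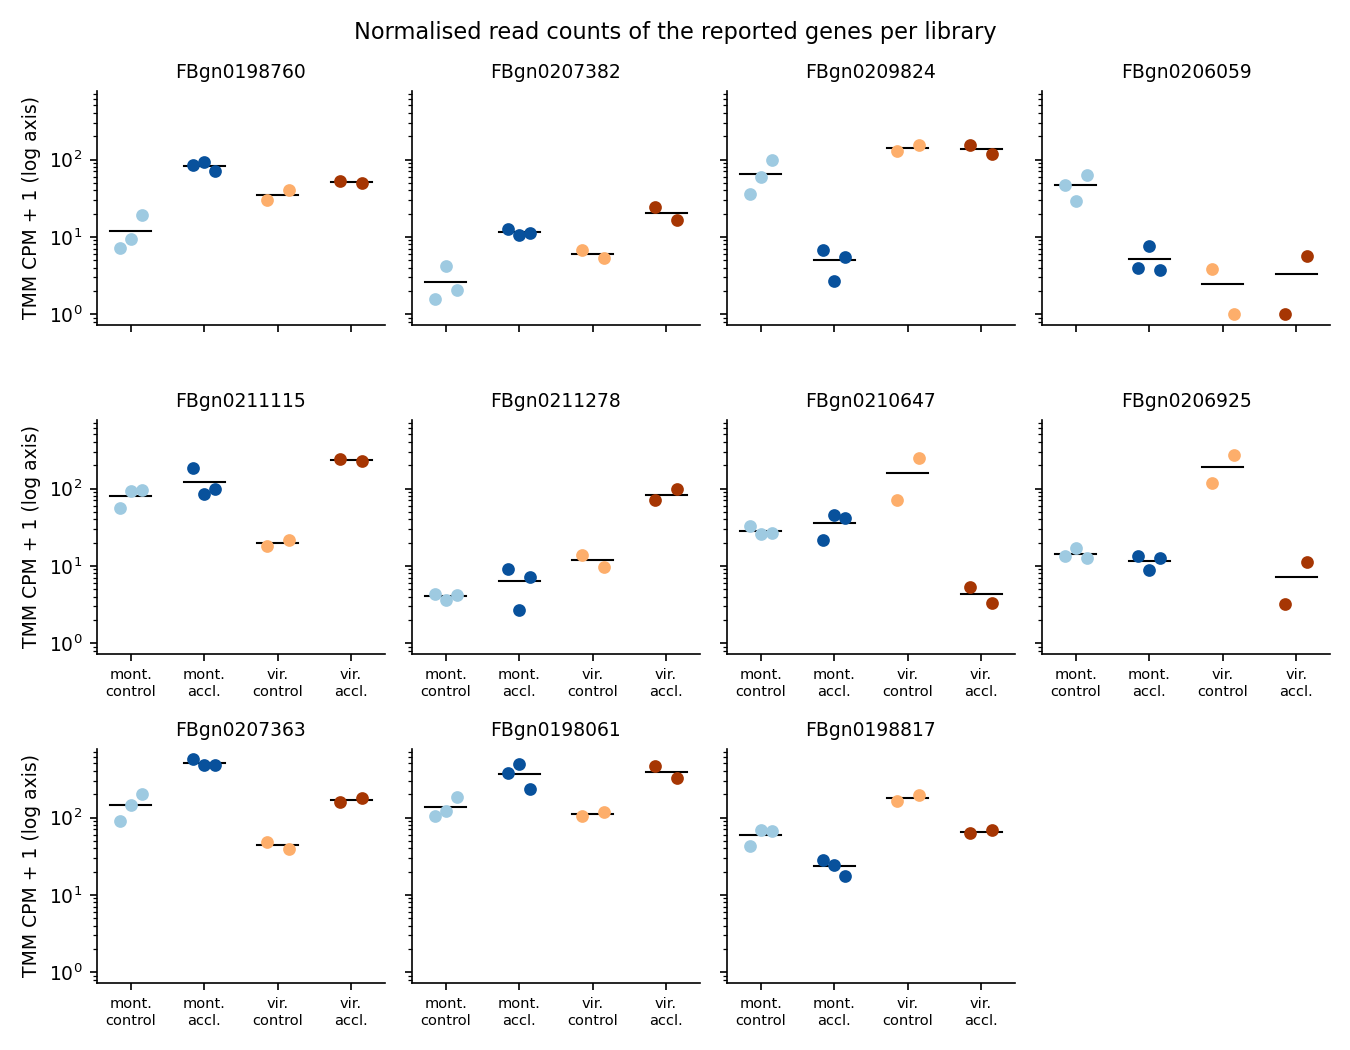
Normalised read counts (CPM over TMM-scaled library sizes, plus 1, log axis) of the 11 reported genes, with 1 point per library and a line at the group mean; mont., D. montana; vir., D. virilis; accl., acclimated. FBgn0209824 fell in D. montana from 63.5 to 4.0 CPM on average and stood at 140 and 136 CPM in D. virilis, while FBgn0211115 rose in D. virilis from 18.9 to 233 CPM.

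The consistency of the response was examined over 7443 genes tested in both species. Of the 140 D. montana and 22 D. virilis calls among them, 4 were shared, against 0.41 for independent lists (Fisher's exact test, one-sided p = 0.00067, adjusted over 5 overlap tests p = 0.0017). All 4 changed in the same direction, 3 upward and 1 downward. The 1 not among the reported genes rose less in D. montana than in D. virilis. Its log2 fold changes were 1.06 (SE 0.22, edgeR adjusted p = 0.024) and 2.29 (SE 0.30, edgeR adjusted p = 0.026). FBgn0207363 rose 3.54-fold in D. montana (log2 fold change 1.82, SE 0.23, edgeR adjusted p = 0.00095) and 3.95-fold in D. virilis (log2 fold change 1.98, SE 0.25, edgeR adjusted p = 0.023). FBgn0198061 rose 2.70-fold and 3.47-fold (edgeR adjusted p = 0.0076 and 0.026). FBgn0198817 fell in both, with log2 fold changes of −1.40 (SE 0.24) and −1.47 (SE 0.23) and edgeR adjusted p of 0.0067 and 0.048. Without D. virilis control 2 none of these 3 genes passed in D. virilis (edgeR adjusted p = 0.151, 0.132 and 0.276, the highest over all alternatives). FBgn0198061 also missed the threshold without D. virilis control 1 (edgeR adjusted p = 0.086) and, in D. montana, without control 2 (edgeR adjusted p = 0.060). FBgn0198817 missed it in D. virilis without control 1 (edgeR adjusted p = 0.077), with DESeq2 size factors (0.059) and with upper quartile scaling (0.0501). A count of 0 genes in opposite directions carries little information, since 0.13 and 0.068 were expected of independent lists. With replicate 2 left out of both D. montana groups, 28 D. montana calls were left among the genes tested in both, and 1 gene was shared (odds ratio 12.5 against 11.9 with every library, Fisher's exact test, one-sided p = 0.083).

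Genes called in D. montana had mostly the same direction of difference in D. virilis. Of the 98 that rose in D. montana, 84 had a log2 fold change above 0 in D. virilis, with a median of 0.55 (1.47-fold) against 1.08 in D. montana, and 40 of them had an unadjusted p under 0.05. Of the 42 that fell, 35 had a log2 fold change below 0 in D. virilis, with a median of −0.73 against −1.38, and 17 had an unadjusted p under 0.05. In the other direction, the 12 genes that rose in D. virilis had a median of 1.89 there and 0.46 in D. montana, and the 10 that fell had −2.57 and −0.36. Genes chosen for their change in one species have smaller changes in another by selection alone, so these medians do not compare the strength of the responses. Together 119 of 140 (85.0%, 95% Wilson interval 78.2 to 90.0, genes not being independent) had the same direction, whereas 59.4% of all 7443 genes had the same sign in both species. The share was 51.4% and 53.6% when the D. virilis libraries were split in the 2 other possible ways.

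Tested as sets in D. virilis, the genes that rose in D. montana shifted upward (limma's camera, preset correlation, adjusted p = 3.4e-14; adjusted p = 0.035 with an estimated correlation; fry adjusted p = 0.013). The genes that fell shifted downward with the preset correlation (adjusted p = 3.7e-12), a call not held with an estimated correlation (adjusted p = 0.127) or by fry (adjusted p = 0.075). The D. virilis sets tested in D. montana shifted upward for the 12 that rose (adjusted p = 2.2e-05) and downward for the 10 that fell (adjusted p = 0.0044), and both calls were lost with an estimated correlation (adjusted p = 0.127 for each). In D. montana 10 of the 12 and 8 of the 10 had the same direction. Adjustment was over the 4 sets. The estimated correlation was 0.00041 for the genes that rose in D. montana, below the preset 0.01, and 0.112 to 0.416 for the other sets. The weaker p-value of the genes that rose in D. montana is therefore not a sign of correlation among them.

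Across the 7443 genes, fold changes in the 2 species correlated with Pearson r = 0.27 and Spearman rho = 0.26, genes not being independent replicates. The largest absolute r among the 29 other joint regroupings of the libraries was 0.17. Without D. virilis acclimated 2 the correlation was 0.17.

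**Figure D3:**
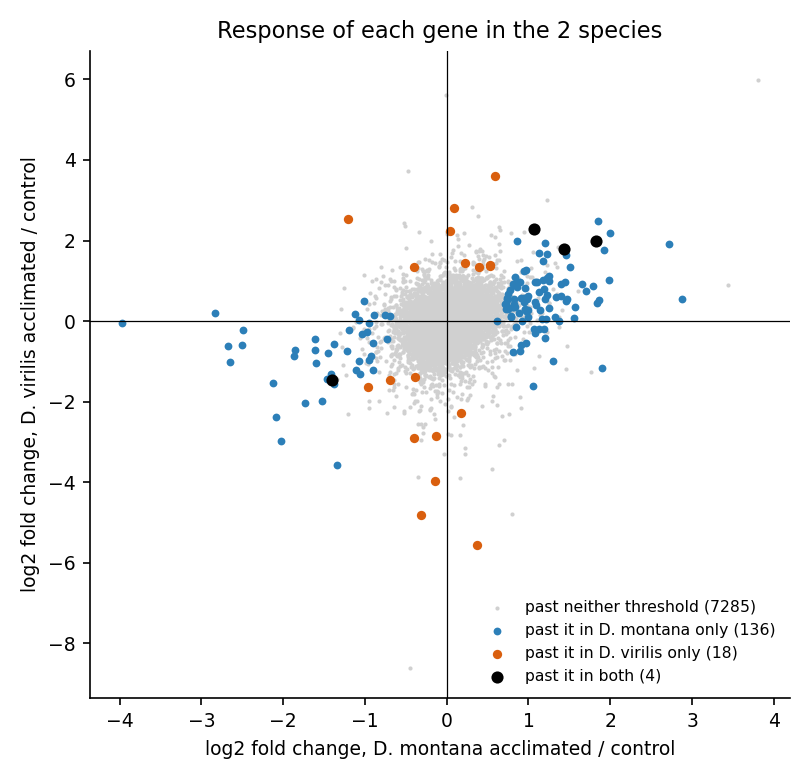
Log2 fold change of acclimated over control libraries in D. montana (horizontal axis) and D. virilis (vertical axis), 1 point per gene tested in both species, coloured by the adjusted p threshold of 0.05. Of the genes past it, 136 passed in D. montana only, 18 in D. virilis only and 4 in both, the 4 lying in the lower left and upper right quadrants.

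The difference in response was tested directly as an interaction, and 22 of 9811 genes passed the threshold. The change was more positive in D. montana for 14 and in D. virilis for 8. The fit took 1 spread per gene for both species, with a common dispersion of 0.033. Fitted alone, D. virilis had 0.063 and D. montana 0.023, so the interaction p-values may understate the D. virilis spread. The differences of the 22 genes ranged from 1.47 to 5.93 log2 units. The species also differed in strain, pool size and stated age, so a difference in response cannot be assigned to species alone. Of these 22 genes, 5 were called in D. montana alone, 9 in D. virilis alone, 0 in both and 8 in neither. The fold changes had opposite signs in the 2 species for 12 of them. Of the 156 genes called in D. montana, 5 differed between the species by this test, and of the 24 called in D. virilis, 9 did. In simulated counts the test recovered 9.41% of differences of 1 log2 unit and 61.9% of 2. Called genes that did not pass it are therefore not shown to respond alike.

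FBgn0209824, which fell in D. montana, had a log2 fold change of −0.05 (SE 0.24) in D. virilis, a difference of −3.94 (SE 0.55, edgeR adjusted p = 0.0024). FBgn0211115, which rose in D. virilis, had a log2 fold change of 0.59 (SE 0.26, edgeR adjusted p = 0.33) in D. montana, and the difference was −3.05 (SE 0.48, edgeR adjusted p = 0.0063). FBgn0210647 and FBgn0206925, which fell in D. virilis, had log2 fold changes of 0.37 (SE 0.26) and −0.32 (SE 0.30) in D. montana, with differences of 5.93 (SE 0.78, edgeR adjusted p = 0.0024) and 4.47 (SE 0.65, edgeR adjusted p = 0.0040). With limma-voom the differences of FBgn0211115, FBgn0210647 and FBgn0206925 did not pass (adjusted p = 0.067, 0.083 and 0.067), and with sample quality weights those of FBgn0210647 and FBgn0206925 had adjusted p of 0.176 and 0.103, their highest. That of FBgn0211115 had an edgeR adjusted p of 0.0507 without D. virilis control 1 and 0.0509 without control 2, while FBgn0209824 passed in every alternative (adjusted p up to 0.033). The response of FBgn0198760 was not shown to differ (difference 2.28, SE 0.47, edgeR adjusted p = 0.059), nor was that of FBgn0207382 (difference 0.73, SE 0.90, edgeR adjusted p = 0.78). For FBgn0206059 the D. virilis libraries held 0 to 6 reads, and for FBgn0211278 the D. montana libraries held 3 to 14, and the differences did not pass the threshold (edgeR adjusted p = 0.24 and 0.25). The number of interaction genes was 14 without D. montana acclimated 2, 43 without D. virilis acclimated 1 and 194 without D. virilis acclimated 2, and without D. montana control 1 the split turned to 10 more positive in D. montana and 12 in D. virilis. With library sizes taken without the 20 most abundant genes it was 35, of which 27 (77.1%) had the more positive change in D. montana, against 63.6% with TMM scaling.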

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

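The tests of read classes were chosen after the values had been seen. The response to acclimation differed between the D. montana and D. virilis libraries for 22 genes in the interaction test, 4 of them reported genes. Species cannot be separated there from strain, pool size or stated age. FBgn0209824 had a difference in log2 fold change, D. montana minus D. virilis, of −3.94 (adjusted p = 0.0024), and FBgn0211115 one of −3.05 (adjusted p = 0.0063). For FBgn0210647 and FBgn0206925 the difference was 5.93 and 4.47 (adjusted p = 0.0024 and 0.0040). The adjusted p-values are edgeR's.

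Outside the gene counts, the mean share of reads aligned to more than 1 place was higher in acclimated than in control libraries by 2.52 percentage points in D. montana and by 6.49 percentage points in D. virilis. The D. montana difference was within the spread of the acclimated pools (SD 2.78, exact permutation test, two-sided p = 0.40). In D. virilis the difference was larger than the SD of either group (1.40 in controls and 0.44 in acclimated flies), and 2 libraries per group allow no test under p = 0.333 in the exact permutation test. It lay above every control of its species in 2 of 3 acclimated D. montana libraries (23.8% and 22.4%, with the other at 18.4%) and in both acclimated D. virilis libraries (82.7% and 83.4%). The acclimated D. virilis files also held more reads as counted there, 14425895 and 16917956 against 6815826 and 9756861 in the controls.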

How the results depend on the processing

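The thinned D. montana fits and the alternatives for the share of genes with the same direction were chosen after seeing the data. With edgeR, TMM scaling and the default filter, 156 genes were called in D. montana, 24 in D. virilis and 22 in the interaction. With no filter beyond 1 count in total the counts were 248, 398 and 80, and with voom and sample quality weights 298, 80 and 12. With a minimum of 1 CPM, 157 genes were called in D. virilis and 50 in the interaction. With the default filter, DESeq2 called 93 genes in D. virilis and 59 in the interaction, and limma-voom 52 and 9. A single fit of all 10 libraries, with 1 spread per gene for both species, called 239 genes in D. virilis and 109 in D. montana. Library sizes without the 20 most abundant genes gave 35 interaction genes. The causes were not tested. Leaving out 1 library gave 72 to 285 genes in D. montana, 4 to 214 in D. virilis and 14 to 194 in the interaction. In D. virilis the lone library left in a group was then assumed to vary like the other group. In D. montana, 2 libraries per group thinned to the D. virilis depth gave a median of 76 genes, from fewer libraries and reads. The replicate block gave 155 genes in D. montana, 42 in D. virilis and 17 in the interaction. The counts of called genes not given here stayed within 1.5 times those of the main setting. Same-numbered libraries did not deviate together (r = −0.23, −0.12 and −0.13 in D. montana, −0.045 in D. virilis). No D. montana control library correlated best with its own number. In D. virilis, deviations from the mean of 2 libraries mirror each other, so both numbers share 1 r and its sign fixes the best partner.

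Shared calls numbered 25 at an adjusted p of 0.10, 58 at an unadjusted p of 0.01 and 17 with DESeq2, of which 24, 55 and 17 had the same direction, against 4 of 4, and 1 to 5 when a D. montana replicate number was left out. The correlation of fold changes ranged from 0.168 to 0.261 when a library was left out. The share of D. montana calls with the same direction in D. virilis ranged from 76.8% to 90.5% in those fits, lowest without D. virilis acclimated 2. Reported genes kept their direction in every alternative that gave them an adjusted p-value, in the comparison in which they were called. DESeq2's Wald test gave none for FBgn0207382 in D. montana and FBgn0211278 in D. virilis, so their direction there was not followed. Fold changes in the comparison where they were not called were not followed. The alternatives for the gene lists were not run, since no list could be matched to identifiers. Simulations took the numbers of libraries, depth and spread of each species together. They recovered 12% of changes of 1 log2 unit in D. virilis and 72.8% in D. montana. The interaction simulation used 1 mean and 1 spread per gene for both species and recovered 9.41%.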

Other observations

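The reduction of D. montana to fewer libraries and reads was chosen after the counts of calls had been seen.

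The fold changes of the species correlated at r = 0.27. There were 30 joint regroupings of the libraries (10 splits of D. montana and 3 of D. virilis). Only 1, the real one, gave an absolute r as large, and the highest of the others was 0.17. This argues against a chance split of the libraries in both species at once. With 1 species held at its real split, 10 or 3 regroupings remain, and the share cannot fall under 0.05. Without D. virilis acclimated 2, r was 0.168. A trend with abundance shared by both comparisons is argued against as well, since the median r within 10 bins of abundance was 0.26 and r was above 0 in 10 of 10 bins, from 0.20 to 0.48. A response shared by the species may underlie the correlation. The stated age, which is higher in the acclimated libraries of both species, stays open and was not tested. It rises by 1 day per library in the order of deposit, and whether it is the true age is uncertain. The share of reads aligned to more than 1 place, on average higher in acclimated libraries of both species, was not tested as a cause either. In D. montana that difference was within the spread of the acclimated pools.

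Fewer genes were called in D. virilis (24) than in D. montana (156). A smaller share of responding genes is not decided: the estimated share of changed genes was 17.3% in D. virilis and 18.1% in D. montana, and the 9 choices of 2 D. montana libraries per group thinned to the D. virilis depth gave 4.83% to 20.6%. The D. virilis value lies above their median of 7.03%, the bound set in advance against this explanation. That bound was a poor one, as seen after the result, since the 3 choices with controls 1 and 2 gave 17.3% to 20.6% and the 6 with control 3 gave 4.83% to 9.52%, so the median follows which controls are paired. A wider spread between D. virilis libraries is a candidate explanation, since their common dispersion was 0.063, above all 9 reduced D. montana fits (0.012 to 0.032). Fewer libraries and lower depth could contribute but are not decided: the reduced D. montana fits called 30 to 304 genes, at most 1.5 times the D. virilis count in 2 of 9. What widens the D. virilis spread, biology or library preparation, was not tested.

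In D. montana the real split of the 6 libraries called 156 genes and the highest of the 9 other splits called 1, so 1 of the 10 splits, the real one, gave as many. With 10 splits the share cannot fall under 0.05.

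At an equal depth of 650517 gene reads, the D. virilis libraries were expected to detect 11774 (control 1), 10210 (control 2), 9616 (acclimated 1) and 10438 (acclimated 2) identifiers. The D. montana libraries were expected to detect 12228 to 12565.

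FBgn0204552, singled out after its values had been seen, held 28851 reads (3.10% of gene reads) in D. virilis control 2 and 30, 42 and 43 reads in the other D. virilis libraries. In the D. montana libraries it held 58 to 99 reads. Other libraries had such identifiers too: with at least 100 CPM and at least 20 times the level of every other library of the species, that level taken as no less than 3 counts, there were 2 in D. virilis control 2, 1 in acclimated 1 and 2 in acclimated 2, and 1 each in D. montana control 2, acclimated 2 and acclimated 3.

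In the controls, mean log2 CPM of the 7443 genes correlated between the species with Pearson r = 0.74 and Spearman rho = 0.70 across genes, which are not independent replicates.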
